A study of Mus musculus with 14 samples.

How the data were processed

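Jejunal RNA of 14 mice was measured, 7 with wild-type LRH-1 and 7 with LRH-1 K289R, each genotype and replicate number being taken from the sample titles and the genotype label. The series title also has the word hepatic, whereas the sample labels name jejunum, and the samples were treated as jejunum. Per the labels' protocols, total RNA was extracted with Trizol, 100 ng was amplified with a whole-transcript kit, and 5500 ng of cDNA was fragmented, labelled with biotin and hybridised. The labels call the samples biological replicates and name no cage, litter, sex or scan day, so none of these could be used as a batch. Mice were housed in shared cages, per the labels' protocols.

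The deposited table gives, for each array, the intensity of 41345 probe sets on a linear scale, from 7.40 to 20050.3 with no missing value. Per the submitters' processing notes, Affymetrix Expression Console was used, and its version, summarisation, background correction and normalization are not given in the sources used here. The near-equal medians (168 to 174) and quartiles of the 14 columns are those of arrays that have been brought to 1 scale, so no further normalization was applied in the main analysis. A normalization of that kind removes any global shift in RNA amount between the genotypes. Any background left in the values compresses the differences of dim genes towards 0. The design had been written for log2 values. As the values proved linear, they were log2-transformed first, as the design provided for.

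Probe sets were named through the platform annotation, with symbols checked by Entrez identifier. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and were left out, and 16010 were unnamed here. A gene was represented by its probe set with the highest mean over all 14 arrays, which gave 22180 genes. The 4170 genes with a mean below the 25th percentile of all probe sets (log2 6.25, an intensity of 75.9) were left out, and 18010 were tested. Of these, 17984 had a position in the gene table of assembly GRCm38.p6. The genome build of the array annotation is not given in the sources used here, so the gene table served for names and for which genes lie near Nr5a2, and no coordinates are printed.

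Differences are K289R minus WT on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, 2-sided, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The standard errors are limma's moderated ones. For Nr5a2, list means and principal components an exact permutation test over all splits of 7 against 7 was run, 2-sided, whose smallest possible p is 0.000583. Genes with an unadjusted p under 0.001 within 10 Mb of Nr5a2 were compared with all other tested genes by Fisher's exact test, 2-sided. On simulated data with 200 changed genes among 18010, the same steps recovered 62.7% of changes of 0.3 log2, 89.6% of 0.5 and 100% of 1, and 13 of 181 calls were unchanged genes. The simulated genes varied independently of each other, unlike those on the real arrays. With fewer changed genes the adjusted threshold would also be harder to pass. These shares may therefore overstate the recovery in the real data.

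Gene lists for LRH-1 targets, intestinal functions, cell types and stress responses were fixed in advance, 41 in all with 613 memberships, of which 528 were tested and the rest are not analysed here. The 38 lists with at least 5 tested genes that were meant for testing went into limma's camera with its preset correlation of 0.01, Benjamini-Hochberg adjusted over lists. Camera with an estimated correlation and fry, in its directional and mixed forms, were run beside it. The mast cell list had 3 tested members, too few for the test. Named genes are Nr5a2, up to 15 genes past the threshold with the largest change each way, those with the smallest p until 20 were named, up to 3 members of each list with the smallest p where none passed, and the members of a list of LRH-1 partners and of a list of sex-linked genes. Genes named outside this rule are said to be singled out after their values were seen. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

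Alternatives were quantile normalization, a shift of each array to 1 median, no filter or a filter at the median on dim genes, the mean over a gene's probe sets, all probe sets as the unit, eBayes with trend and robust options, array weights, a replicate block, the list means of B cells, pancreatic acinar cells or smooth muscle as a covariate, leaving out each array in turn, looser thresholds, other list tests, and another distance or p limit around Nr5a2. Added after seeing the data were the distal small intestine list mean as a covariate, a fit without the 4 arrays with a Fabp6 log2 level above 8, and a fit without the genes within 20 Mb of Nr5a2. The smallest root mean square difference between any pair of arrays was 0.160 on the log2 scale, so no array was a copy of another. The first 3 principal components held 20.6%, 18.1% and 11.5% of the variance, and exact permutation p values for the genotypes were 0.182, 0.334 and 0.0425. All 14 arrays had Xist near background (mean 6.39 in WT and 6.42 in K289R) and high levels of the Y-linked genes Uty (9.60 and 9.75), Kdm5d (9.33 and 9.36) and Eif2s3y (9.65 and 9.56). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.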

Results

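Jejunal RNA from 14 mice was hybridised to Affymetrix whole-transcript arrays, with 1 array per mouse. The mice carried either wild-type LRH-1 (WT, 7 mice) or LRH-1 K289R (7 mice). LRH-1, encoded by Nr5a2, is a nuclear receptor of liver, pancreas and intestine that acts on genes of bile acid and cholesterol handling and on crypt renewal. In K289R an arginine takes the place of a lysine known as an acceptor site for the small protein modifier SUMO, so the comparison of the 2 genotypes asks how jejunal transcript levels differ when that site is altered. The mice were between 19 and 21 weeks of age, had free access to food and were killed at 7 am. Each array gave an intensity for 41345 probe sets, with median intensities of 168 to 174 per array, and 18010 genes entered the tests. Arrays of the same genotype correlated with r between 0.981 and 0.994, and WT with K289R arrays with r between 0.979 and 0.994. The number of arrays limits the precision, with a median standard error of 0.067 on the log2 scale for the difference between genotypes.

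The transcript of Nr5a2 itself differed little between the genotypes. Its log2 intensity was 10.32 ± 0.18 (SD, n = 7) in WT and 10.18 ± 0.19 (SD, n = 7) in K289R. The WT arrays ran from 10.06 to 10.60 and the K289R arrays from 9.83 to 10.39. The difference of −0.14 (SE 0.092, 95% interval −0.33 to 0.06) was not past the threshold (limma adjusted p = 0.685), and the exact permutation p was 0.201. A point mutation need not alter the transcript level, so this value does not check the genotype labels. Genes for regulators that act with or beside LRH-1 did not pass the threshold either. Prox1, a corepressor of LRH-1, differed by 0.04 (SE 0.078), the corepressor gene Nr0b2 by 0.25 (SE 0.119) and the enterocyte regulator Hnf4a by −0.02 (SE 0.051). Of 14 measured genes in the list of LRH-1 and these regulators, Nr5a2 itself among them, with Gata4, Gata6, Cdx1, Cdx2, Hnf4g, Ncoa1, Ncoa2, Ncoa3, Ppargc1a and Nr5a1, 0 passed limma's test over all genes tested and 0 adjusted over the list alone, and 1 of them, Nr0b2, had an unadjusted p under 0.05.

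Between the genotypes, 8 genes passed the threshold, 3 higher and 5 lower in K289R. Insig2, whose product holds back cholesterol synthesis at the endoplasmic reticulum, rose by 0.63 (SE 0.105), and Cdc73, a subunit of the PAF1 transcription elongation complex, rose by 0.56 (SE 0.070). Glrx2, a mitochondrial glutaredoxin, rose by 0.36 (SE 0.056). The genes that fell were Car4, a membrane-anchored carbonic anhydrase of the enterocyte surface, Muc4, a transmembrane mucin, Tnnt2, a troponin T gene, Rnpep, which encodes aminopeptidase B, and 2010010A06Rik. Car4 differed by −0.72 (SE 0.098), a fold of 0.609, and Tnnt2 by −0.71 (SE 0.094), a fold of 0.610.

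Muc4 went from 9.96 ± 0.19 (SD, n = 7) to 9.40 ± 0.18 (SD, n = 7), and Rnpep from 11.47 ± 0.05 (SD, n = 7) to 11.03 ± 0.10 (SD, n = 7). The adjusted p values from limma were 0.00190 for Rnpep, 0.00389 for Cdc73, 0.00497 for Tnnt2 and 0.00579 for Car4. For Glrx2, Muc4, 2010010A06Rik and Insig2 they were 0.0260, 0.0271, 0.0274 and 0.0343. All 7 K289R arrays lay on the same side of the WT mean for each of the 8 genes. In 7 of the 8, all but Muc4, the arrays of the genotypes did not overlap. Over all genes tested, 30 showed no overlap, where chance gives a share of 0.0583%, or 10.5 genes. In all, 1528 genes had an unadjusted p under 0.05 against 900.5 expected by chance, and 73 had one under 0.001 against 18.0.

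**Figure D1:**
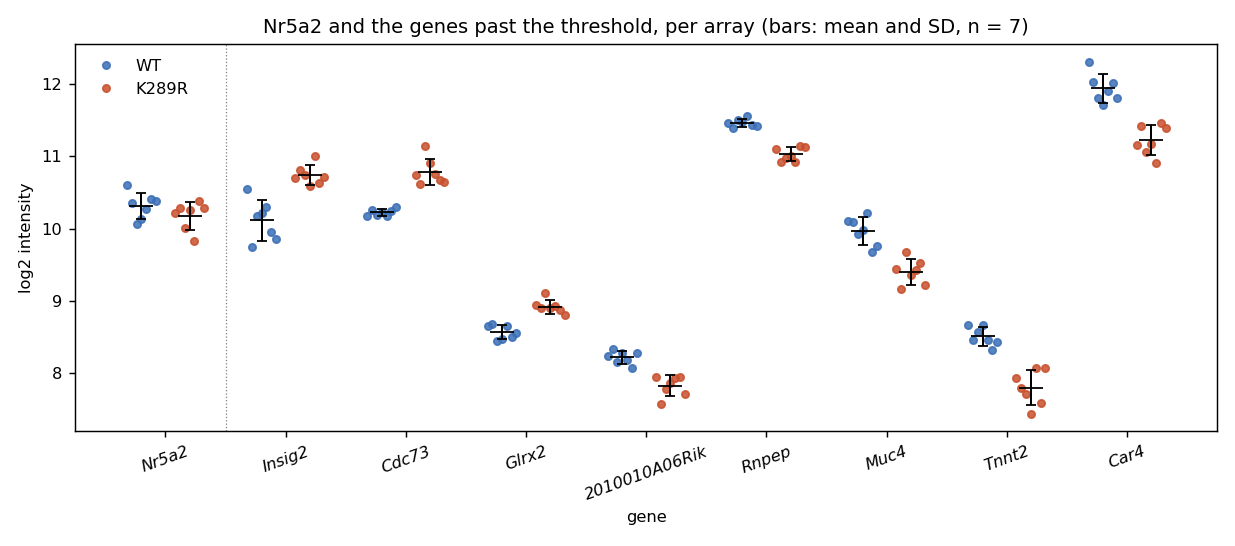
Log2 intensity (vertical axis) of Nr5a2 and of the 8 genes past the threshold (horizontal axis) on each array, with 7 WT (blue) and 7 K289R (red) arrays per gene and marks and bars for mean and SD. Nr5a2 overlaps between the genotypes, whereas Car4 lies between 11.71 and 12.31 in WT and between 10.91 and 11.46 in K289R.

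A further 12 genes with the smallest p values did not pass. Gsdmc3, a gasdermin gene, had the largest difference among them, 1.12 (SE 0.208, adjusted p = 0.0678), with levels of 8.65 ± 0.42 (SD, n = 7) in WT and 9.77 ± 0.49 (SD, n = 7) in K289R. Ctse, the gene of the aspartic protease cathepsin E, differed by 0.77 (SE 0.147), Snrpe, a core splicing protein gene, by 0.44 (SE 0.078), Ddx59 by 0.30 and Clic4 by 0.25. Lower in K289R were the epithelial transcription factor gene Elf3 with −0.38 (SE 0.066, adjusted p = 0.0507), Uap1 with −0.42, Banp with −0.48, Fcgrt, the neonatal Fc receptor, with −0.36, Olfr401 with −0.36, Gm10144 with −0.31 and Rabif with −0.27. At an adjusted p under 0.1, 18 genes counted, 8 higher and 10 lower. Rnpep, Cdc73, Tnnt2 and Car4 passed in each of 14 fits that left out 1 array. With the smooth muscle mean as a covariate Car4 (adjusted p = 0.0952) and Tnnt2 (0.0524) did not pass. Their differences in that fit were −0.70 (SE 0.129) and −0.73 (SE 0.124), near those without the covariate but with larger standard errors. Glrx2 passed in 8 of the fits that left out 1 array, all but those without WT replicates 3, 4, 6 and 7 and K289R replicates 1 and 4 (adjusted p up to 0.0693). Muc4 passed in 6, without WT replicates 5, 6 and 7 and K289R replicates 3, 5 and 6 (0.0728 at most in the others), 2010010A06Rik in 6, without WT replicates 5 and 6 and K289R replicates 1, 2, 5 and 6 (0.0891), and Insig2 in 3, without WT replicates 1 and 5 and K289R replicate 6 (0.0984). With every array shifted to 1 median, 2 genes were higher and 8 lower, and 4 genes passed without WT replicate 3, WT replicate 4 or K289R replicate 4 and 14 without K289R replicate 5.

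Some named genes short of the threshold passed it in refits. Elf3 did so in 11 of 27, of which 4 left out 1 array: WT replicate 6 (adjusted p = 0.0441) or K289R replicates 3 (0.0259), 5 (0.0464) or 6 (0.0482). Its highest adjusted p was 0.210. Snrpe passed in 9 of 27, 2 of them without WT replicate 1 (0.0175) or K289R replicate 2 (0.0414), and had a highest adjusted p of 0.145. Uap1 passed in 9 of 28, 1 of them without K289R replicate 3 (0.0143), and reached 0.421 at most. With array weights Elf3 (0.0122), Snrpe (0.0214), Uap1 (0.00893), Gsdmc3 (0.0153), Ddx59 (0.0255) and Fcgrt (0.0251) passed. Gsdmc3 also passed without WT replicate 5 (0.0468) or K289R replicates 3 (0.0444) or 5 (0.0259), Ddx59 (0.0134) and Fcgrt (0.0252) without K289R replicate 5, and Olfr401 (0.0497) without K289R replicate 6. Banp passed with the smooth muscle covariate (0.0382), Clic4 with the filter at the median (0.0446), and Rabif with quantile normalization (0.0406) and with shifted arrays (0.0369). Of genes named further on, Me1 passed without WT replicate 1 (0.0364), Sycn without WT replicate 7 (0.0395) and with the pancreatic covariate (0.0366), and Fgf15 with the latter (0.0181). The pancreatic covariate is a list mean that includes Sycn itself, so for Sycn that fit is not an independent check.

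The genes with low p values were concentrated on chromosome 1 around Nr5a2. Of the 8 genes past the threshold, 5 are on chromosome 1, and Rnpep, Cdc73, Tnnt2 and Glrx2 lie within 10 Mb of Nr5a2 in the gene table of assembly GRCm38.p6. The others are Car4 on chromosome 11, Muc4 on 16 and 2010010A06Rik on 18. A knock-in can keep a stretch of the genome of the embryonic stem cells around the altered gene, and the test of this neighbourhood was set up for that reason. Within 10 Mb, 12 of 141 tested genes (8.51%) had an unadjusted p under 0.001, against 60 of 17842 elsewhere (0.336%). The odds ratio was 27.5 (95% interval 13.2 to 53.3, Fisher's exact p = 3.45e-13).

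The 12 genes went both ways, 8 higher and 4 lower in K289R. Besides the 4 that passed they were Elf3, Snrpe, Ddx59, Rabif, Ctse, Kcnt2, Kdm5b and Pm20d1. Pm20d1 had a difference of 0.48 (SE 0.114), and it, Kcnt2 and Kdm5b were singled out after their values were seen. In the order of tested genes, Ddx59 was 5 places from Nr5a2 on 1 side and Kcnt2, Cdc73 and Glrx2 were 14, 15 and 17 places away on the other. Ctse was 87 places away. Between 10 and 20 Mb, 1 of 82 genes had a p this low, and this was Insig2. Over the rest of chromosome 1 there were 6 of 829 (0.724%), and on the other chromosomes 53 of 16931 (0.313%). Against all chromosome 1 genes outside the 10 Mb window, those between 10 and 20 Mb included (7 of 911), its odds ratio was 11.96 (95% interval 4.25 to 36.5, Fisher's exact p = 4.76e-07). Here too genes were counted as independent units. When the 223 genes within 20 Mb of Nr5a2 were left out of the test, a step chosen after the data were seen, Car4 passed and no other gene did, and Muc4 and 2010010A06Rik each had an adjusted p of 0.0629.

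**Figure D2:**
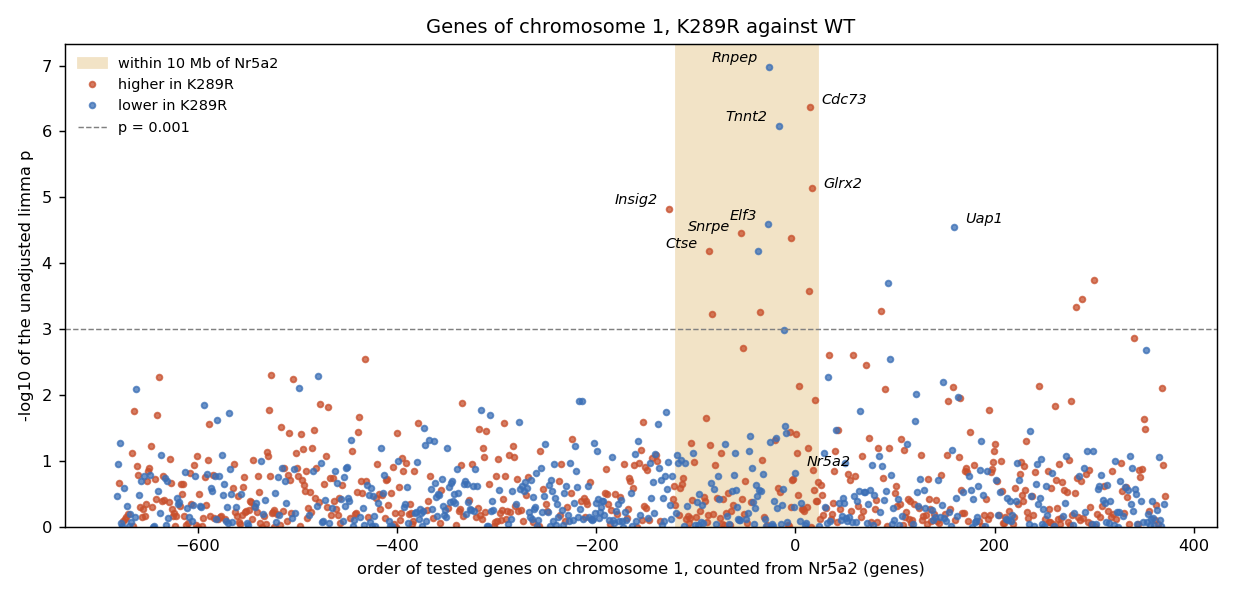
Each point is a tested gene of chromosome 1, placed by its order from Nr5a2 (horizontal axis, in genes) and by −log10 of its unadjusted limma p (vertical axis), in red if higher and in blue if lower in K289R. The shaded band holds the genes within 10 Mb of Nr5a2, where 12 of 141 lie above the dashed line.

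Among 41 gene lists fixed for jejunum and LRH-1, the groups closest to the receptor showed little difference with all arrays included. With the preset correlation 7 lists passed, those of smooth muscle, fibroblasts and matrix, type I interferon, antigen presentation, T cells, fatty acid synthesis and ribosomal proteins. With an estimated correlation 0 lists passed (lowest adjusted p = 0.846). Of the LRH-1 target list, 17 genes were measured, 7 higher and 10 lower, with a median of −0.01. With limma 0 of the 17 passed over all genes tested and 0 adjusted over the list alone, 1 had an unadjusted p under 0.05, and the list itself did not pass (camera adjusted p = 0.802). Hp differed by 0.28 (SE 0.148) and Abcg5 by −0.06 (SE 0.063). The 17 measured genes of reverse cholesterol transport and lipoproteins, such as Pltp (0.18, SE 0.105) and Apoe (0.09, SE 0.097), had a median of −0.0017 (adjusted p = 0.703). Cholesterol synthesis genes had a median of 0.01 over 19 members (adjusted p = 0.802), with Insig1 at 0.13 (SE 0.148). The mean of this list was 10.46 on WT replicate 1 and at most 9.72 on the other WT arrays. Without that array the list passed upwards at the preset correlation (camera adjusted p = 1.84e-05), a fit not run with an estimated correlation. WT replicate 1 was also high for the LRH-1 target list mean. No member of any list passed over all genes tested.

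Smooth muscle genes were higher in K289R in 12 of 14 cases, with a median of 0.21. Adjusted over the list alone 8 of the 14 rose, among them Synm (0.30, SE 0.066), Acta2 (0.19, SE 0.048) and Myh11 (0.27, SE 0.076). The genes of fibroblasts and matrix were higher in 12 of 12 cases, with a median of 0.20, and Vim (0.33, SE 0.089), Dcn (0.30, SE 0.087) and Lum (0.32, SE 0.098) rose when adjusted over the list alone. A second Vim probe set differed by 0.15. With camera's preset correlation both lists passed, with adjusted p = 1.92e-08 for smooth muscle and 4.91e-07 for fibroblasts and matrix. With the smooth muscle mean as a covariate Dcn was at 0.16 and Lum at 0.13, and the median of their list at 0.10. Neither call held with a correlation estimated from the arrays (adjusted p = 0.846 with an estimated correlation, for both). Before adjustment over the lists, that camera p was 0.0354 for smooth muscle and 0.0612 for fibroblasts and matrix.

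Interferon and immune genes were also higher on average. Of the type I interferon response genes 17 of 18 were higher, with a median of 0.19, and 1, Rsad2 (0.43, SE 0.117), rose when adjusted over the list alone. The list median was 0.11 without K289R replicate 5. Mx2 differed by 0.27 (SE 0.094) and Ifit3 by 0.13 (SE 0.059). Of the genes for antigen presentation and the interferon gamma response 11 of 12 were higher, with a median of 0.31, led by H2-DMa (0.58, SE 0.283), H2-DMb1 (0.47) and H2-Eb1 (0.45). Of the T cell and intraepithelial lymphocyte genes 14 of 16 were higher, with a median of 0.26, such as Cd3g (0.58, SE 0.335), Cd3e (0.40, SE 0.264) and Cd8b1 (0.16), and in these lists 0 genes passed limma's test adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05. The adjusted p values with the preset correlation were 3.69e-05, 0.00152 and 0.0199 in that order, and each was 0.846 with an estimated correlation. These lists varied widely between mice of 1 genotype, with list means from 9.35 to 10.35 in WT and from 9.52 to 10.51 in K289R for antigen presentation.

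**Figure D3:**
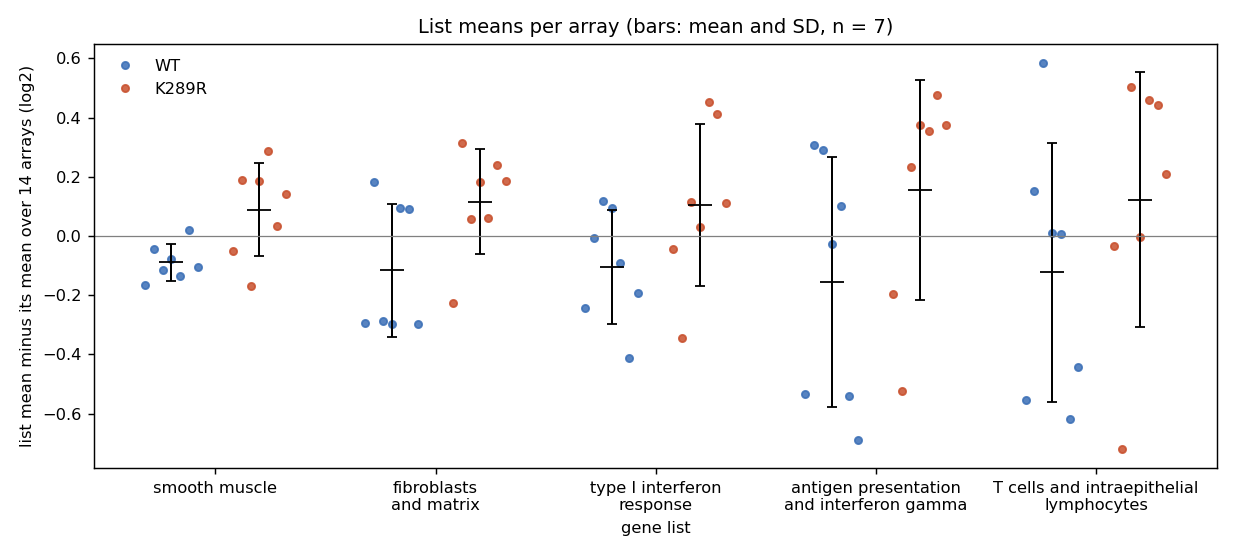
Mean log2 level of 5 gene lists (horizontal axis) on each array, as the difference from that list's mean over 14 arrays (vertical axis, log2), with 7 WT (blue) and 7 K289R (red) arrays and marks for mean and SD. The means are higher in K289R for each list, and the arrays of the genotypes overlap in all 5.

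The other lists past the threshold with the preset correlation were fatty acid synthesis, higher in 9 of 13 genes with a median of 0.11 (adjusted p = 0.0410), and ribosomal proteins, lower in 14 of 14 genes with a median of −0.089 (adjusted p = 0.00624). Both were at an adjusted p = 0.846 with an estimated correlation. In fatty acid synthesis Me1, the cytosolic malic enzyme, rose when adjusted over the list alone, by 0.94 (SE 0.207), and Scd1 differed by 0.56 (SE 0.250) and Elovl5 by 0.20 (SE 0.074). Rps9, Rplp0 and Rpl13 differed by −0.14, −0.17 and −0.14. In total 7 of 38 lists passed with the preset correlation and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. By fry 0 passed (2 at an unadjusted p under 0.05 for 1 direction, 6 for either direction), as did 0 by the exact permutation test of the list mean (2 unadjusted). At the preset correlation 85 of 100 splits of the 14 arrays gave as many lists as the real one, which is among them, and T cells, fatty acid synthesis and ribosomal proteins lost their calls without WT replicate 6 (among other arrays), with adjusted p values up to 0.149, 0.216 and 0.116 over the fits that left out 1 array. Over these fits the list medians ran from 0.15 to 0.41 for T cells, from 0.05 to 0.18 for fatty acid synthesis and from −0.10 to −0.05 for ribosomal proteins. The last was −0.055 with the mean over all probe sets of a gene (adjusted p = 0.0435).

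**Figure D4:**
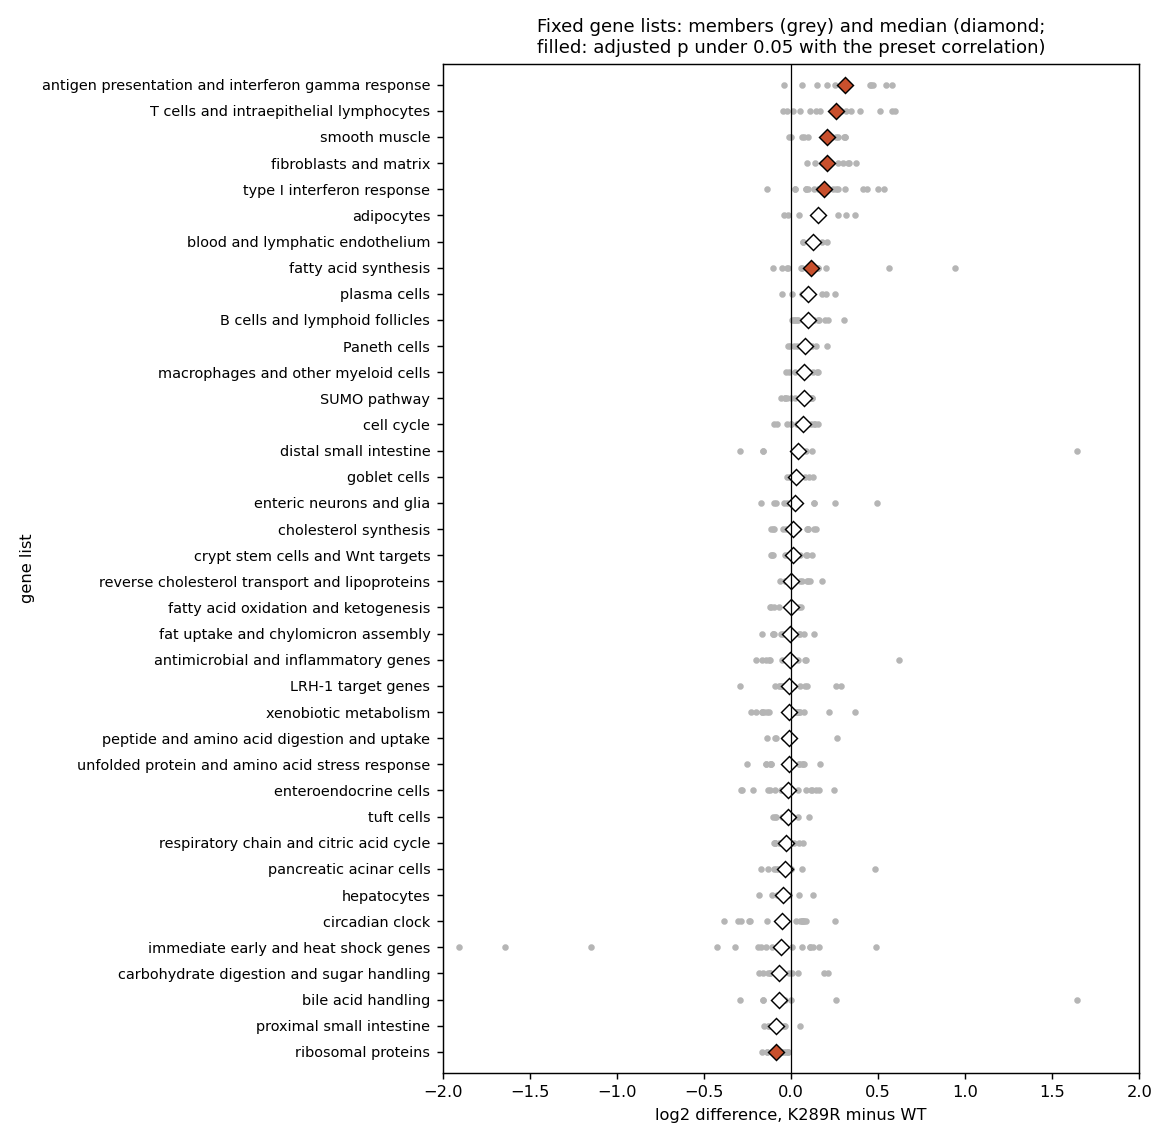
Log2 difference, K289R minus WT (horizontal axis), of the measured members (grey points) and their median (diamonds) for each of 38 tested gene lists (vertical axis). Filled diamonds mark the 7 lists past the threshold with the preset correlation, of which antigen presentation has the highest median, 0.31, and ribosomal proteins the lowest, −0.089.

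Several single genes rose or fell when adjusted over their own list alone, in lists that did not pass. Fgf15, the enterokine that feeds back on hepatic bile acid synthesis, rose by 1.64 (SE 0.405), from 7.79 ± 0.65 (SD, n = 7) in WT to 9.43 ± 1.09 (SD, n = 7) in K289R, with an adjusted p of 0.00759 over the bile acid list alone and 0.227 over all genes. It was above the WT mean on 6 of 7 K289R arrays, and a dimmer second probe set differed by 0.12. The mean over both probe sets differed by 0.88. Of the 9 measured bile acid genes 2 were higher, Fgf15 and Nr0b2 (0.25, SE 0.119), and 7 lower, with Slc51a at −0.16 (SE 0.169) and the list median at −0.071 (camera adjusted p = 0.738). With 1 array left out Slc51a ran from −0.25 to −0.021, and its highest WT array was WT replicate 1 at 12.29. The ileal gene Fabp6, chosen after its values were seen, was between 9.18 and 12.52 on 4 arrays, WT replicates 1 and 6 and K289R replicates 2 and 7. It was between 6.09 and 6.63 on the other 10. The distal small intestine list had a median of 0.04 (adjusted p = 0.441), with Nts at 0.12, and the proximal list one of −0.086 (adjusted p = 0.280), with Slc11a2 at −0.16 and Gip at −0.13.

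**Figure D5:**
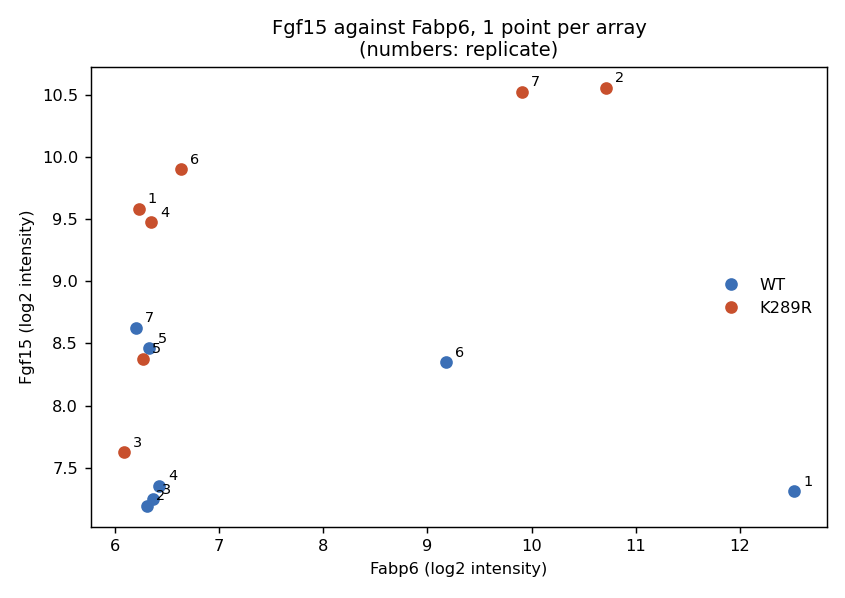
Log2 intensity of Fgf15 (vertical axis) against that of Fabp6 (horizontal axis) on each of 14 arrays, 7 WT (blue) and 7 K289R (red), with replicate numbers beside the points. K289R replicates 2 and 7, with Fabp6 at 10.71 and 9.91, have the highest Fgf15 levels, 10.56 and 10.52. WT replicate 1, with the highest Fabp6 at 12.52, has an Fgf15 level of 7.31, and WT replicate 6, with Fabp6 at 9.18, one of 8.35.

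Among circadian clock genes, Per3 (−0.29, SE 0.076) and Nr1d2 (−0.39, SE 0.106) fell when adjusted over the list alone, and Dbp was at −0.24 (SE 0.084). Nr1d2 was at −0.24 (SE 0.093) without the 4 arrays with Fabp6 signal. Arntl, which peaks opposite to these genes and was singled out after its value was seen, was at 0.25 (SE 0.097), and the list as a whole had a median of −0.052 (adjusted p = 0.178). The heat shock genes Hsph1 (−1.15, SE 0.260), Hspa1b (−1.91, SE 0.552) and Hspa1a (−1.64, singled out after its value was seen) fell and Atf3 (0.49, SE 0.128) rose when adjusted over the list alone. Hspa1b spanned 8.59 to 12.68 in WT and 8.48 to 9.10 in K289R, and the immediate early and heat shock list had a median of −0.057 (adjusted p = 0.132). Chga (−0.29, SE 0.082) fell and Scg3 (0.25, SE 0.076) rose among 18 enteroendocrine genes (median −0.02, adjusted p = 0.784), with Scg2 at 0.16. By the same count Sycn, a pancreatic acinar gene, rose by 0.48 (SE 0.112), Kit, 1 of 3 measured mast cell genes (median 0.082), rose by 0.22 (SE 0.075), or 0.14 with the smooth muscle mean as a covariate, while Mcpt1 of the same list was at −0.33 (SE 0.282), and the hepatocyte gene Apoh fell by 0.19 on the log2 scale. With 1 array left out Mcpt1 ran from −0.60 to −0.22. Over all genes tested, the adjusted p values of the genes in this paragraph that rose or fell ran from 0.142 for Hsph1 to 0.413 for Kit.

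Absorptive and metabolic lists did not pass. The median was −0.0076 for fat uptake and chylomicron assembly (adjusted p = 0.667), with Mogat2 at −0.097, Plin2 at −0.10 and Plin3 at −0.10. It was −0.0022 for fatty acid oxidation and ketogenesis (adjusted p = 0.784), with Ppara at −0.12, and −0.070 for carbohydrate digestion (adjusted p = 0.480), with Slc2a5 at −0.19, G6pc at 0.19 and Khk at −0.12. Peptide and amino acid uptake had a median of −0.012 (adjusted p = 0.329), with Slc7a9 at −0.14 and Slc7a7 at −0.094, xenobiotic metabolism −0.01 (adjusted p = 0.784), and the respiratory chain and citric acid cycle −0.032 (adjusted p = 0.118), with Uqcrc1 at −0.094. The first probe set of Cyp2c55 differed by 0.36 and its second by −0.071. The unfolded protein list had a median of −0.012 (adjusted p = 0.400), with Herpud1 at −0.25 and Hspa5 at −0.14, and the SUMO pathway list one of 0.071 (adjusted p = 0.118), with Pias3 at 0.12. At the preset correlation the SUMO pathway list passed in 5 of 28 refits, whereas with all arrays and an estimated correlation it was at an adjusted p of 0.846, as was the respiratory chain list. These 5 were the fits with array weights (adjusted p = 0.0334), with the smooth muscle mean as a covariate (0.0247), and without WT replicate 1 (0.0311), WT replicate 2 (0.0391) or K289R replicate 5 (0.0372). The respiratory chain list passed downwards in 3, without WT replicate 1 (0.0311), WT replicate 6 (0.0466) or K289R replicate 3 (0.0187).

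Epithelial and other cell type lists that did not pass were as follows. Crypt stem cell and Wnt target genes had a median of 0.0093 (adjusted p = 0.991), with Smoc2 at −0.11, and cell cycle genes one of 0.065 (adjusted p = 0.150), with Top2a at 0.16 and Mcm3 at 0.12. Paneth cell genes were at 0.079 (adjusted p = 0.280), goblet cell genes at 0.03 (adjusted p = 0.373), tuft cell genes at −0.021 (adjusted p = 0.493) and antimicrobial and inflammatory genes at −0.0091 (adjusted p = 0.528), with Duox2 at 0.62 (SE 0.305). Enteric neuron and glia genes had a median of 0.019 (adjusted p = 0.703), with Vip at 0.49 (SE 0.196), Snap25 at 0.25 and Gfap at −0.17. Endothelial genes were higher in 9 of 9 cases (median 0.13, adjusted p = 0.0504) and B cell genes in 12 of 12 (median 0.098, adjusted p = 0.260). Myeloid genes (median 0.075, adjusted p = 0.111), with Mrc1 at 0.15, and plasma cell genes (median 0.098, adjusted p = 0.118), with Prdm1 at 0.20 and Irf4 at 0.25, did not pass. Of the lists for neighbouring tissues, adipocyte genes had a median of 0.16 (adjusted p = 0.187), with Fabp4 at 0.37, hepatocyte genes −0.046 (adjusted p = 0.260) and pancreatic acinar genes −0.038 (adjusted p = 0.461). The means over the pancreatic list were 7.96 in both genotypes, and those over the hepatocyte list 7.46 in WT and 7.42 in K289R.

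Further lists that did not pass in the main analysis did so in some of 28 refits, all at the preset correlation of 0.01. With all arrays and an estimated correlation, which was 0.743 for the endothelial and 0.717 for the cell cycle list, the lists of this paragraph were at an adjusted p of 0.846, and cholesterol synthesis at 0.963. The refits were not run with an estimated correlation. The endothelial list passed upwards in 12. These were the fits with arrays shifted to 1 median (adjusted p = 0.0220), no filter on dim genes (0.0379), the mean over probe sets (0.0480), array weights (0.0334), a replicate block (0.0188) and the pancreatic mean as a covariate (0.0301), and without the genes within 20 Mb of Nr5a2 (0.0479). The others were without WT replicate 2 (0.00690), WT replicate 5 (0.00388), WT replicate 6 (0.0138), K289R replicate 1 (0.00869) or K289R replicate 5 (0.0126), and the highest of the 28 adjusted p values was 0.505. Plasma cell genes passed upwards in 4, with array weights (0.0435) and without WT replicate 2 (0.0172), WT replicate 5 (0.0256) or K289R replicate 5 (0.0272). Myeloid genes did so in 4, with a replicate block (0.0444) and without WT replicate 2 (0.0171), WT replicate 5 (0.00668) or K289R replicate 1 (0.00538). Cell cycle genes passed upwards in 3, with array weights (0.00782), with the smooth muscle mean as a covariate (7.86e-05) and without K289R replicate 5 (5.05e-06). B cell genes did so in 2, with the smooth muscle mean as a covariate (0.0298) and without K289R replicate 4 (0.00735). Goblet cell genes passed without K289R replicate 3 (0.0478) and adipocyte genes without K289R replicate 6 (0.00674), both upwards. Of lists given earlier, cholesterol synthesis (1.84e-05) and distal small intestine (0.0311) passed upwards without WT replicate 1. The immediate early and heat shock list passed downwards in 4, with the smooth muscle mean as a covariate (0.0106) and without WT replicate 4 (0.0490), WT replicate 5 (0.0256) or K289R replicate 5 (0.0228).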

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

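Of the tests in this part, those of the genes left with 20 Mb around Nr5a2 removed, of LRH-1 targets over the genome, of a linked stretch of chromosome, of probe mismatch, of the muscle wall and of other bile acid receptor targets were chosen only after the result was seen.

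Single arrays stood far from the other 6 of their genotype in 21 of 380 groups of 7 examined (149 named genes and 41 list means in each genotype), by a gap above Dixon's 95% limit. Chance flags about 1 in 20 groups, so this number is close to what chance gives. WT replicate 1 accounted for 6 of them, being high for the cholesterol synthesis list mean (10.46), Mvd (9.19), the bile acid handling list mean (9.88), Slc51a (12.29), Slc7a9 (11.91) and the LRH-1 target list mean (9.20). WT replicate 2 was high for the immediate early and heat shock list mean (10.48), and WT replicate 6 was low for Mx2 (6.53). Among K289R arrays, replicate 3 was low for Mogat2 (11.62), Atoh1 (10.25), Cdx1 (9.005) and the peptide and amino acid uptake list mean (12.21). Replicate 5 was low for Manf (7.90), the cell cycle list mean (9.08) and the ribosomal protein list mean (10.50), and replicate 1 was low for Vim (11.24) and Pltp (8.26). Replicate 7 was low for Khk (10.73) and high for Mcpt1 (8.18), replicate 2 was low for Bmi1 (6.26) and replicate 4 was low for Pnliprp1 (6.79).

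The count of 8 genes past the threshold was reached by 1 of 100 splits of the 14 arrays, the real one. The highest other split gave 2 genes. The 100 splits were a sample of those possible, so chance is an unlikely source of this count but is not excluded. For genes beyond 10 Mb of Nr5a2 the real split gave 4, the highest other gave 2, and 1 of 100 splits reached 4. The adjustment there still included the genes of the window, whose low p values in the real split loosen the cut-off. The splits were thus not compared on equal terms for that count. With the genes within 20 Mb left out, the real split gave 1 gene, the highest other gave 2, and 4 of 100 splits gave at least 1, the real one included. As many genes with an unadjusted p under 0.05 as the real 1528 came from 9 of 100 splits (highest 3116), so chance cannot be excluded for that count. For the 7 gene lists at the preset correlation, 85 of 100 splits gave as many and the highest other gave 22, so chance cannot be excluded for that count.

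The first pattern is the cluster of low p values around Nr5a2, where 12 genes had a p under 0.001 and the highest other split gave 4, with 1 of 100 splits reaching 12. An effect of altered LRH-1 on targets spread over the genome would leave the share near Nr5a2 like that elsewhere, whereas the lower bound of the odds ratio was 13.2. That bound restates the cluster, so it is not a separate test of this explanation. A probe mismatch to a variant on the K289R haplotype lowers a signal, which argues against it for the 2 genes of the window that rose past the threshold, Cdc73 and Glrx2, though a variant on the WT haplotype, not tested, would give such a rise. For the 4 low-p genes that fell (Rnpep, Tnnt2, Elf3 and Rabif) a mismatch and a lower transcript level cannot be told apart, since no probe sequences were compared with variants. A stretch of chromosome linked to Nr5a2 that differs between the groups, such as one retained from embryonic stem cells, may account for the cluster. So may a local effect of the altered locus. The odds ratio against all chromosome 1 genes outside the window (lower bound 4.25) restates the cluster and would be high for either, so they cannot be told apart.

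The second pattern is the higher level of smooth muscle and matrix genes in K289R. A smooth muscle p as small as the real one (9.30 as −log10 p, highest other 15.7) came from 7 of 100 splits, so chance cannot be excluded. A larger share of muscle wall in the K289R pieces remains a candidate explanation. It predicts a rise of the enteric neuron and glia list mean of 0.077 from its within-group slope on the smooth muscle mean (0.43, SE 0.13). The measured rise of 0.058 (SE 0.040) differed from this by −0.019 (SE 0.038). That rise is too imprecise to be told apart from no rise or from the predicted one, so it does not decide. For fibroblasts and matrix the slope of 0.69 (SE 0.46) predicts 0.123 against a measured 0.231, and the excess of 0.108 (SE 0.132) is too imprecise to tell. An effect of genotype on the gut wall was not separately tested.

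The third pattern is the higher Fgf15 in K289R. A more distal piece of intestine in the K289R mice was tested with the mean of the other distal genes as a covariate. The Fgf15 difference was 1.67 (SE 0.388) with it and 1.64 (SE 0.405) without it. That mean differed by only −0.062 between the genotypes, with Fabp6 at 12.52 on WT replicate 1. The covariate could thus hardly move the difference, and the test does not decide on position. Without the 4 arrays with Fabp6 signal the difference was 1.22 (SE 0.421, limma adjusted p = 0.677). Of these 4, K289R replicates 2 and 7 had the highest Fgf15 levels of all arrays (10.56 and 10.52), while WT replicates 1 and 6 had 7.31 and 8.35. A raised bile acid receptor response across its target genes may underlie the higher Fgf15, but 1 of 3 other measured targets was higher (Nr0b2, 0.25), with Slc51a at −0.16 (SE 0.169) and Fabp6 at −0.16 (SE 0.994). On WT replicate 1 Slc51a was at 12.29 and Fabp6 at 12.52, against at most 11.51 and 9.18 on the other WT arrays. The count of 1 of 3 thus leans on that array. The spread of Fabp6 keeps that explanation open. The second Fgf15 probe set, at 0.12, was dimmer, with a mean of 7.19 against 8.61, and did not show the rise.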

How the results depend on the processing

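The distal list as a covariate and the settings without the 4 arrays with Fabp6 signal and without the genes within 20 Mb of Nr5a2 were chosen only after the data were seen. Near Nr5a2 the odds ratio stayed above 1 and past the threshold in 29 of 29 alternatives (5.31 to 37.6), and the Nr5a2 difference stayed below 0 and short of the threshold in 28 of 28 (−0.18 to −0.077, adjusted p 0.469 to 0.844). Genes higher in K289R numbered 3 and lower 5. The number higher was 5 with a filter at the median, 6 with array weights, 1 with the B cell and 6 with the pancreatic covariate, and 1 over all probe sets. The number lower was 8 with quantile normalization, with arrays shifted to 1 median and with array weights, and 3 with the smooth muscle covariate and without the 4 arrays with Fabp6 signal. Looser thresholds gave 8 higher and 10 lower (adjusted p under 0.1) or 34 and 20 (unadjusted p under 0.01 and 1.3-fold). Without the genes within 20 Mb of Nr5a2 it was 0 higher and 1 lower: Cdc73, Glrx2, Insig2, Rnpep and Tnnt2 were left out by construction, and Muc4 and 2010010A06Rik, with the same differences, lost the call through the adjustment (adjusted p = 0.0629); 1494 genes had an unadjusted p under 0.05. For the other counts the cause was not tested. With the replicate number as a block, limma called 0 higher and 0 lower, with 1465 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0539, while 9 lists passed. Same-numbered arrays showed little sign of pairing. They correlated between −0.15 and 0.17 around the group means, 1 of 7 pairs over 0.1, and 0 arrays matched their own number best. The labels do not say what the numbers stand for, so a shared batch is not excluded. Leaving out 1 array gave 1 to 7 higher and 3 to 7 lower genes. The total was 4 without WT replicate 3, WT replicate 4 or K289R replicate 4 and 14 without K289R replicate 5; higher counts were 5 without WT replicate 1 or 5 and 1 where the total was 4, and lower counts 3 without WT replicate 1, 2, 3 or 4 or K289R replicate 4 or 7. Apart from the block, Car4 (adjusted p = 0.0952), Tnnt2 (0.0524), Muc4 (0.147), 2010010A06Rik and Insig2 (0.136 each) lost the call with the smooth muscle covariate, Glrx2, Insig2 and 2010010A06Rik (0.0528 each) with the B cell covariate, those 3 and Muc4 (0.125 each) without the 4 arrays with Fabp6 signal, and Insig2 (0.0548) with shifted arrays. With the smooth muscle covariate the differences were −0.70 (SE 0.129) for Car4, −0.73 (SE 0.124) for Tnnt2 and 0.65 (SE 0.139) for Insig2. They were −0.37 (SE 0.083) for 2010010A06Rik and −0.40 (SE 0.099) for Muc4, which moved most, from −0.57. Lists past the threshold numbered 7, 5 to 11 with 1 array left out (11 without WT replicate 2 or 5), 0 with camera's estimated correlation and 0 by fry. T cells lost the call with array weights (0.134) and without WT replicates 1, 6, 7 and K289R replicates 3, 5, 6, 7 (adjusted p up to 0.149), fatty acid synthesis with the median filter (0.0784), the smooth muscle (0.0852) or distal covariate (0.0657) and without WT replicates 6, 7 and K289R replicates 2, 4, 7 (up to 0.216) and ribosomal proteins with array weights (0.0633), the smooth muscle covariate (0.249), without the 4 arrays with Fabp6 signal (0.0958) and without WT replicate 6 and K289R replicate 5 (up to 0.116). Type I interferon and antigen presentation passed in 28 of 28 refits at the preset correlation, and the fibroblast list lost its call with the smooth muscle covariate alone (adjusted p 8.53e-10 to 0.124 over alternatives). Of 219 refits of called genes 163 kept the call, 56 lost it and 0 turned sign, and of 3898 refits of the other named genes 46 passed and 27 turned sign, in 13 genes. With the smooth muscle covariate these were Adipoq (−0.025), Apoe (−0.012), Atoh1 (−0.025), Clca1 (−0.00083), Flt4 (−0.014), Lyve1 (−0.044), Nts (−0.095), Snap25 (−0.021), Eif2s3y (0.19) and Ncoa2 (0.00096). Ncoa2 also turned with array weights (0.0014), the distal covariate (0.0033) and without the 4 arrays with Fabp6 signal (0.0099), Hnf4a with array weights (0.015) and Xist without those 4 arrays (−0.020). With 1 array left out, Ncoa2 ran from −0.013 to 0.011, Hnf4a from −0.039 to 0.0053, Eif2s3y from −0.22 to 0.0029, Prox1 from −0.0039 to 0.077 and Xist from −0.017 to 0.056. The cause of these reversals was not tested. Signal over background limits genes near the dim limit of log2 6.25.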

Other observations

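Lists of immune and interferon genes varied together between mice, within both genotypes. Across the 14 arrays the T cell list mean followed the antigen presentation list mean, with Pearson's r = 0.893 (permutation p = 0.00012) and Spearman's rho = 0.701 (permutation p = 0.00646). The value was 0.849 without the 2 arrays farthest from the median, and within genotypes r was 0.919 in WT (exact permutation p = 0.00675) and 0.849 in K289R (exact permutation p = 0.0258). Antigen presentation followed the type I interferon list with r = 0.834 (permutation p = 6e-05) and rho = 0.793 (permutation p = 0.00114), 0.805 without the 2 farthest arrays, and 0.803 and 0.841 within WT and K289R. The T cell list mean ran from 7.94 to 9.14 in WT and from 7.84 to 9.06 in K289R, against a difference between the genotypes of 0.25 in the mean.

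Smooth muscle genes followed those of enteric neurons and glia with r = 0.742 (permutation p = 0.00236) and rho = 0.714 (permutation p = 0.0052), 0.839 without the 2 farthest arrays. Within genotypes r was 0.733 in WT (exact permutation p = 0.0569) and 0.711 in K289R (exact permutation p = 0.0730), so the relation was not past the threshold in either. They followed fibroblast and matrix genes with r = 0.602 (permutation p = 0.0249) and rho = 0.635 (permutation p = 0.0167), 0.600 without the 2 farthest arrays. Within genotypes the latter was 0.529 in WT (exact permutation p = 0.227) and 0.449 in K289R (exact permutation p = 0.320), so this relation too was not past the threshold in either. These 4 relations were picked after the list means had been seen, and the Benjamini-Hochberg adjusted p values of r were 0.00024, 0.00024, 0.00315 and 0.0249 in the order given.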
